A study of Arabidopsis thaliana with 12 samples.

How the data were processed

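Whole seedlings of Arabidopsis thaliana aged 10 days were compared on two-colour Agilent arrays of design 021169, with 3 arrays for each of 4 groups: 35S:STOP1 against Col-0 and a stop1 knockout against Col-0, in control and after 200 mM NaCl for 24 h. Groups and dyes were taken from the labels. The mutant RNA carried Cy5 on replicates 1 and 3 and Cy3 on replicate 2 of each group. Per the file headers, the deposited scanner files were written by Agilent Feature Extraction 10.7.3.1 with protocol GE2_107_Sep09 and hold spot intensity values that had not been normalized between channels, beside Agilent's own processed signal, which is background-subtracted and dye-normalized. The deposited series matrix holds log2 ratios. Set against the scanner files, each of its columns correlated at 1 with the log2 of processed mutant over processed Col-0 signal (median absolute difference 0.00248 to 0.00252), so its scale and direction are known and its sign had been turned on the swapped arrays. Its column medians were 0.13, -0.10 and 0.06 in the overexpressor in control, 0.08, -0.18 and 0.13 in the knockout in control, 0.11, -0.16 and 0.18 in the overexpressor in NaCl and 0.08, -0.19 and 0.10 in the knockout in NaCl, so it had not been centred. What else the authors did to these values is not given in the sources used here.

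The scanner files carry no column of mean spot signals, so the median signals were used in place of the planned mean signals, with the median background, in the alternative without background correction too. They were corrected with normexp (offset 50) in limma 3.58.1 under R 4.3.3 and normalized by loess within each array. Control spots and spots that the scanner software marks as outliers had weight 0, and the latter were left out. No spot was saturated. Spots of 1 probe were averaged, and of several probes of a gene the one with the highest mean brightness stood for it. A gene was tested when its probe was well above background in at least 3 of the 24 channels, which left out 7404 of 29030 genes. Of 43603 different probes, 5190 carry no locus code and were set aside. Of the loci, 28595 were found in the TAIR10.1 reference table, used for names only, and 10499 have a symbol there other than the locus code. No coordinates are printed because the array was designed on another build.

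For the ratios, 1 limma fit covered all 12 arrays, with an effect per group coded by the dye of the mutant and a gene-specific dye effect shared by all arrays, because 2 of the 3 arrays of a group have the same orientation. A dye effect passed the threshold in 5040 genes. Because replicate 2 is the swapped array of every group, this term cannot be told apart from an effect common to the replicate 2 arrays. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, and all adjusted p values of genes come from limma. The difference between conditions was a contrast in the same fit. The median SE of a log2 ratio was 0.096, with 7 residual degrees of freedom. For the salt response, loess and Aquantile normalized single channels of Col-0 were used, those with the same condition and replicate number on overexpressor and knockout arrays being averaged, since the series counts 3 wild type replicates, and the fit held condition and dye (3 residual degrees of freedom). That such channels are 1 sample is an assumption. After condition and dye were taken off they correlated across genes at -0.779 to 0.053, and different-numbered ones at -0.61 to 0.488. Taking these off lowers such correlations by itself, most for replicate 2, which holds all Cy5 channels of Col-0. The values therefore do not favour the assumption, nor settle it. The 12 arrays lay on 3 slides of 4. The first held the overexpressor in control and 1 knockout control array, the second 2 arrays each of the knockout in control and the overexpressor in NaCl, and the third 1 array of the overexpressor in NaCl and the 3 of the knockout in NaCl.

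Before the data were examined, 25 gene lists with 444 entries were fixed, of which 10 entries were dropped because the reference did not tie the name to the locus. They cover STOP1-dependent genes, GABA and malate metabolism, CBL and CIPK genes, ion transport, abscisic acid, phosphate, iron, nitrate, cell wall loosening, photosynthesis, root markers, guard cell markers, seed storage, senescence, salicylic acid, jasmonate and ethylene, hypoxia, heat shock, reactive oxygen, flavonoids, glucosinolates, auxin, the clock, reference genes and ribosomal proteins. Only 7 ribosomal proteins could be found. Some genes stand in more than 1 list, such as EXPA7 under roots and cell wall and GDH2 under STOP1-dependent genes and GABA metabolism. Lists were tested with camera at a preset correlation of 0.01 and again with an estimated one, adjusted over the lists of a comparison. The rule for named genes was also fixed then. It takes STOP1; in each ratio comparison and the salt response the 10 largest rises and 10 largest falls past the threshold that had the same sign on all 3 arrays, were well above background on all 3 in the brighter genotype and have a symbol; the STOP1-dependent genes in the ratio comparisons; up to 4 called members, by size of change, of each other list that passed or had 3 or more called members; and the 5 largest rises and 5 largest falls between conditions by the same criteria without that of equal sign. SE is the standard error of the fit and n counts arrays. A list that did not pass is reported by its adjusted p, without a direction of the list.

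On simulated data with the real variances and dye effects and 200 changed genes per group among 21389, the fit found 94.7% of the genes changed by 1 on the log2 scale for the overexpressor in control, 94.7% for the knockout in control, 97.0% and 93.8% in NaCl, and 97.1% of those in the salt response among 21619 genes. At a change of 0.5 these shares were 60.5%, 69.3%, 45.0%, 54.7% and 75.8%. For the differences between conditions they were 90.3% (overexpressor) and 87.1% (knockout) at a change of 1, and 29.9% and 34.0% at 0.5. The share of false calls was between 2.4% and 8.0%. The alternatives were other background corrections, normalizations, filters, gene summaries and designs, the series matrix, the slide as a block, the replicate number as a block and leaving out each array in turn. Figures were drawn with matplotlib.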

Results

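Gene expression was measured on 12 two-colour arrays hybridised with RNA of whole Arabidopsis seedlings aged 10 days. Each array set a line with altered STOP1 against the wild type accession Col-0. STOP1 is a zinc finger transcription factor known for its part in tolerance of protons and aluminium. The lines were 35S:STOP1, which overexpresses the gene from a viral promoter, and a stop1 knockout, and each was compared with Col-0 without added salt (control) and after 200 mM NaCl for 24 h. There were 3 arrays in each of the 4 groups, and replicate 2 of each group had the dyes exchanged. Per array, between 66.6% and 72.5% of the spots were well above background in Cy3 and between 46.6% and 55.7% in Cy5, the lowest Cy5 share being that of replicate 2 of the knockout in control. The labels call the replicates biological without saying how the seedlings were grown apart, so the p-values measure the spread between these samples only, and 3 arrays per group limit the precision. Of 29030 genes on the array, 21626 were bright enough to be tested.

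STOP1 itself (AT1G34370) was examined first. It rose 42.6-fold in the overexpressor in control (log2 ratio 5.41 ± 0.12 SE, n = 3 arrays, limma adjusted p = 2.92e-08) and 17.9-fold in NaCl (4.16 ± 0.12). In the knockout it fell 6.21-fold in control (-2.64 ± 0.12) and 5.05-fold in NaCl (-2.34 ± 0.12). All 12 arrays had the sign that their labels give. The rise in the overexpressor was smaller in NaCl than in control, with a difference of -1.25 ± 0.17 and an adjusted p of 0.00316. On these arrays the log2 level in the overexpressor was 15.83 to 16.15 in control and 15.13 to 15.48 in NaCl. That in Col-0 was 10.28 to 10.90 in control and 10.76 to 11.53 in NaCl, so part of the difference lies in the Col-0 channel. On the knockout arrays the Col-0 level showed no such rise, with 11.05 to 11.42 in control and 10.91 to 11.19 in NaCl. In Col-0 the level of STOP1 with NaCl differed from control by 0.17 ± 0.08 (n = 3 values per condition), which did not pass the limma test (adjusted p = 0.121) and was -0.03 with the slide as a block. The position of the probe against the disrupted part of the gene was not examined.

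**Figure D1:**
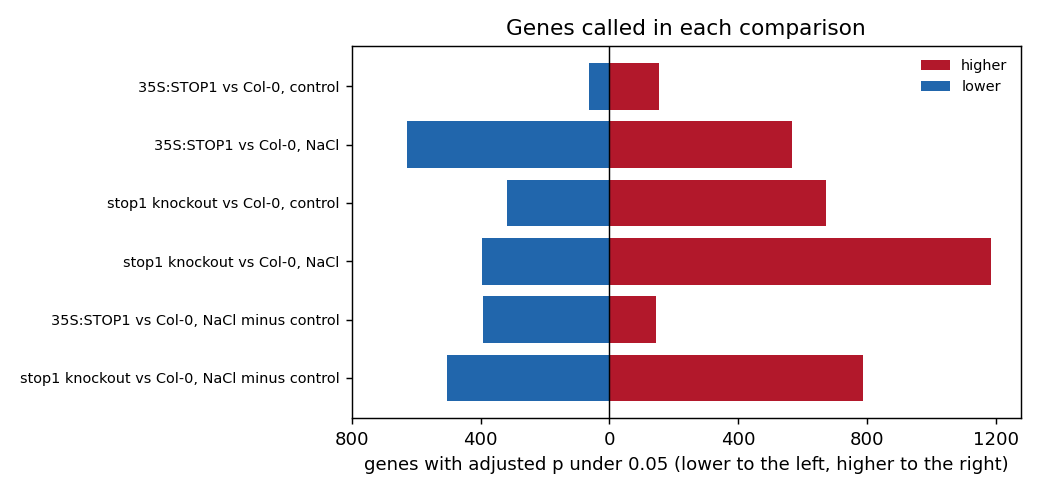
Number of genes with an adjusted p under 0.05 in each comparison, with genes higher in the line than in Col-0 as bars to the right and lower genes as bars to the left. The knockout in NaCl had the longest bar, 1186 genes higher.

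The first comparison asked what overexpression of STOP1 changed in seedlings without added salt. ALMT1, the root malate transporter gene of aluminium tolerance, rose 2.94-fold (log2 1.56 ± 0.09 SE, n = 3), and HAK5, a high-affinity potassium transporter gene, rose by 1.25 ± 0.10. Among genes with a symbol that met the naming rule, PCC1, XTH24, MOP10, CYP705A12, RHS13, PRP3 and CYP708A2 completed the 10 largest rises with STOP1, between 0.96 and 1.40. The largest falls among these genes were those of PS2, a phosphatase gene of phosphate starvation (4.36-fold lower), of GASA6 (-1.19 ± 0.15), of MGD3, a galactolipid synthase gene (-1.18 ± 0.11), and of CYP78A5 (-1.06 ± 0.06). In all, 219 of 21616 genes passed the test, 155 higher and 64 lower. PCC1 and HAK5 were well above background in Col-0 on 2 of 3 arrays. Calls were lost for MOP10 without replicate 2 (0.0691), PRP3 without replicate 1 and 3 (0.0679 and 0.061) and GASA6 without replicate 2 (0.109) (adjusted p values in parentheses).

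Of the 15 measured genes known from earlier work to depend on STOP1, 3 rose in the overexpressor in control (ALMT1, HAK5 and GDH2, a glutamate dehydrogenase gene, 0.61 ± 0.06) and none fell, and adjusted over the list alone 5 rose. Some members of this list, CIPK23 among them, may be known from studies of these same lines, and for those it is not independent evidence of a direction. The list moved up against the other genes (camera adjusted p = 4.59e-08, and 0.014 with an estimated correlation). Phosphate starvation genes moved down, with 4 of 18 lower (PS2, MGD3, GDPD1 at -0.95 and SPX1 at -0.62), 8 of them adjusted over the list alone, and an adjusted p of 3.47e-11. Root tissue markers moved up (adjusted p = 2.92e-11), with 5 of 20 higher, 10 adjusted over the list alone. These included EXPA7, an expansin gene of root hairs (0.84 ± 0.11), and COBL9 (0.81 ± 0.12). Jasmonate and ethylene defence genes moved up with 3 of 22 members past the test, AOC1, PR3 and PR4, between 0.43 and 0.48, and 5 adjusted over the list alone (adjusted p = 7.83e-06). Glucosinolate genes moved up as a list (median 0.19, adjusted p = 3.08e-06) with no single member past the test over all genes and 4 adjusted over the list alone. With an estimated correlation the phosphate, root, jasmonate and glucosinolate lists stayed at adjusted p values of 0.00938, 0.00646, 0.014 and 0.00938. The lists of reactive oxygen genes (median 0.08, adjusted p = 0.000352, GSTU25 higher by 0.79 and 6 higher adjusted over the list alone) and of iron deficiency genes (median 0.09, adjusted p = 0.0463, 1 member higher adjusted over the list alone) were lost with an estimated correlation, at adjusted p = 0.0608 and adjusted p = 0.116. The other 18 lists had adjusted p values between 0.0768 and 0.985, but the guard cell list passed without replicate 1 (0.0315) and the salicylic acid list within 1 slide (0.012). BT2 fell by 0.76 while NIA1, a nitrate reductase gene, and NRT2.1 (above background in Col-0 on 2 of 3 arrays) rose by 0.52 and 0.43, and EXPA1 fell by 0.62 while EXPA18 and TCH4 rose by 0.53 and 0.81. The count depended on the arrays and the slide. It was 101, 61 and 93 without replicate 1, 2 and 3 of the group, 138 with the slide as a block and 2 within the slide that held all 3 arrays, where the phosphate list (median -0.33) and the root list (0.27) passed. Median centring in place of loess left 8 genes (50% higher, against 70.8% here), Agilent's processed signals gave 346 and a fit without a dye effect 127. The iron list did not pass with the slide as a block (adjusted p = 0.054), within the slide (0.096) or without replicate 1, 2 or 3 (0.0724, 0.145 and 0.071). Single calls were lost for AOC1 without replicate 1, 2 and 3 (0.271, 0.394 and 0.15), PR3 without replicate 2 and 3 (0.183 and 0.0573) and PR4 without replicate 2 (0.0855) (adjusted p values in parentheses). The same held for COBL9 without replicate 1, 2 and 3 (0.124, 0.104 and 0.114), EXPA7 without replicate 2 (0.151) and EXPA1 without replicate 2 (0.0632). It also held for EXPA18 without replicate 2 and 3 (0.32 and 0.15), NIA1 without replicate 2 (0.0674) and NRT2.1 without replicate 1, 2 and 3 (0.0606, 0.399 and 0.132).

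In control seedlings of the knockout, MRD1 fell by 2.90 ± 0.18 on the log2 scale (n = 3), GSTF14 by 2.29 ± 0.17, ASPGB1, an asparaginase gene, by 1.79 ± 0.07, NEET by 1.78 ± 0.08, NRT1.5, a nitrate transporter gene of the xylem, by 1.66 ± 0.07 and AAH by 1.15 ± 0.07. CHX17, a cation and proton exchanger gene, rose by 2.63 ± 0.06, bHLH38, an iron deficiency regulator gene, by 2.61 ± 0.16 and ORG1 by 2.07 ± 0.18. CYP705A12 (2.60 ± 0.08), THAS1, a thalianol synthase gene (2.15 ± 0.12), CYP705A5 (2.00 ± 0.13) and CYP708A2 (1.74 ± 0.07), all of triterpene clusters expressed in roots, rose as well, as did YLS9, BAM5 and CYP97B3. In all, 992 of 21626 genes passed, 674 higher and 318 lower. MRD1 was well above background in the knockout on 1 of 3 arrays, and bHLH38, YLS9 and BAM5 were so in Col-0 on 2 of 3.

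Of the 15 genes known to depend on STOP1, 7 fell in the knockout in control and none rose, and 8 fell adjusted over the list alone (camera adjusted p = 2.81e-11, and 0.00712 with an estimated correlation). PGIP1, a polygalacturonase inhibitor gene, fell by 1.64 ± 0.09, the nitrate transporter gene NRT1.1 by 1.36 ± 0.27, GDH2 by 0.73 ± 0.06, GDH1 by 0.69 ± 0.11 and CIPK23, a kinase gene of potassium and nitrate transport, by 0.62 ± 0.10, with CIPK23 well above background in the knockout on 1 of 3 arrays only. ALMT1 and STOP2 (AT5G22890) were not well above background in the knockout. Their fitted log2 ratios of -1.55 and -1.21 passed the limma test (adjusted p = 8.8e-06 and 0.000467), but the sizes are not known. Of 18 iron deficiency genes and ferritins, 10 rose and 1 fell (adjusted p = 1.16e-08). These included bHLH39 (1.68 ± 0.08), bHLH100 (1.54 ± 0.09), both above background in Col-0 on 2 of 3 arrays, and the ferric reductase gene FRO3 (1.24 ± 0.13). Of 16 nitrate genes, 5 fell and 1 rose (adjusted p = 0.000461 for the list). NIR1 stood at -1.02 ± 0.12, and BT2, picked after its value was seen, rose by 0.84. All 20 root tissue markers lay above 0 and 10 rose (adjusted p = 1.06e-13), with TIP2;3 (1.51 ± 0.32), CASP1 (0.93 ± 0.08), EXPA7 (0.84 ± 0.11) and CASP2 (0.74 ± 0.07). Of 22 jasmonate and ethylene genes, 6 rose (adjusted p = 7.52e-05 for the list), with PR3 at 1.08 ± 0.06. Adjusted over the list alone, 11 iron genes, 1 nitrate gene, 16 root markers and 8 jasmonate genes rose, and 1 iron gene and 5 nitrate genes fell. With an estimated correlation these 4 lists stayed at adjusted p values of 0.00426, 0.039, 0.00348 and 0.0285. The lists of GABA and malate metabolism (6 of 18 lower, PPC3 at -1.39 and NADP-ME2 at -0.86), of photosynthesis (none of 29 past the test over all genes, median -0.10), of reactive oxygen genes (4 higher, GSTU25 at 1.57, and 1 lower) and of 7 ribosomal protein genes (median 0.21) passed with adjusted p values of 0.0172, 0.00498, 0.0338 and 0.016. All of these 4 were lost with an estimated correlation, at adjusted p = 0.195. In these lists 2 GABA and malate genes rose and 7 fell adjusted over the list alone, 5 reactive oxygen genes rose and 2 fell, 1 ribosomal gene rose, and no photosynthesis gene passed. Without replicate 2 the photosynthesis, reactive oxygen and ribosomal lists did not pass (each at 0.121), nor did the reactive oxygen list without replicate 1 (0.0564). The other 16 lists had adjusted p values between 0.0603 and 0.854, but the senescence list passed without replicate 3 (0.0421) and the glucosinolate list within 1 slide (0.0322). The count was 483, 433 and 584 without replicate 1, 2 and 3, 731 with the slide as a block, 3647 (84.8% higher, against 67.9%) when fitted on these 3 arrays alone and, in limma, 0 within the slide that held 2 of them, where 1443 genes had an unadjusted p under 0.05 and STOP1 itself did not pass (log2 ratio -2.69). With median centring 201 genes passed and without a dye effect 620. From Agilent's processed signals, 53.0% of 1712 called genes were higher, against 67.9% here, and within that slide the iron and root lists passed upward (medians 0.65 and 0.46). The limma test missed the threshold for NRT1.1 without replicate 1, 2 and 3 (0.113, 0.225 and 0.0713), GDH1 without replicate 2 (0.128) and CIPK23 without replicate 2 (0.0898) (adjusted p values in parentheses). The same held for PPC3 without replicate 1 and 3 (0.0835 and 0.0753) and TIP2;3 without replicate 1, 2 and 3 (0.0748, 0.356 and 0.0713).

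**Figure D2:**
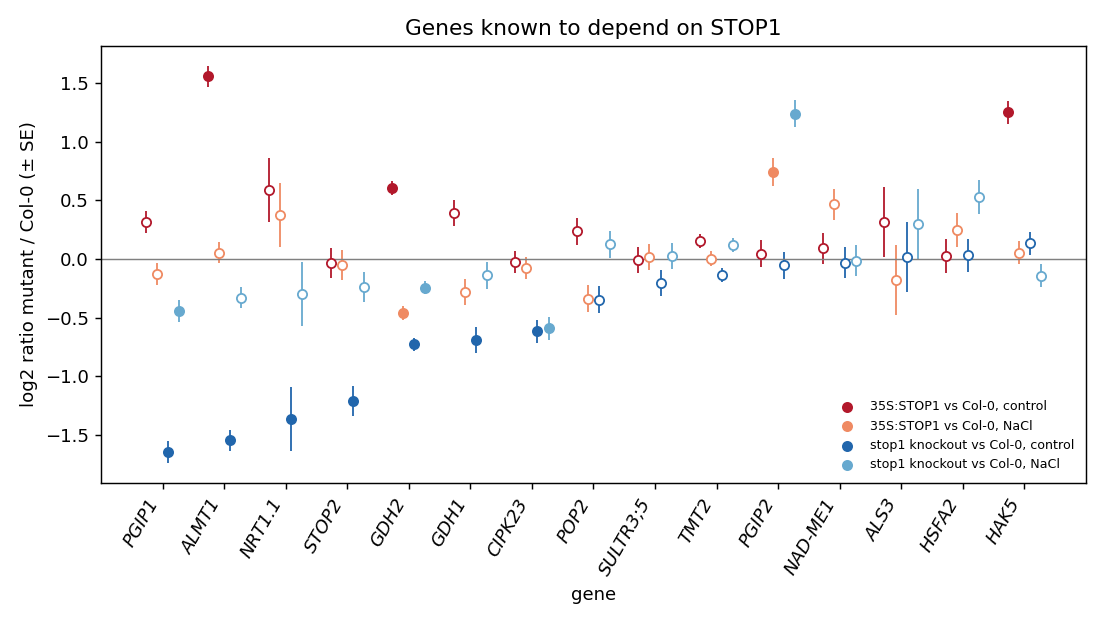
Log2 ratios against Col-0 (vertical axis, with SE bars, n = 3 arrays) of the 15 measured genes known to depend on STOP1, for both lines in control and in NaCl. Filled points passed the test at an adjusted p under 0.05 and open points did not, with ALMT1 at 1.56 in the overexpressor in control, and the points of ALMT1 and STOP2 in the knockout, of HAK5 in the knockout in NaCl and of SULTR3;5 in both lines in NaCl are fitted values of signals not well above background.

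After NaCl, SEN1, a gene known from dark-induced senescence, was 3.49 ± 0.17 lower on the log2 scale in the overexpressor than in Col-0 (n = 3). GLYI7 fell by 2.42 ± 0.09, NIT2 by 2.31 ± 0.09, the beta-amylase gene BAM5 by 2.19 ± 0.11 and BXL1, a xylosidase gene, by 2.04 ± 0.08, and J8 was 4.35-fold lower. TPS04, a terpene synthase gene, rose by 2.06 ± 0.27, PGL5 by 1.68 ± 0.12, ERF13 by 1.52 ± 0.08, AGP30 by 1.48 ± 0.13, ERF1, an ethylene response factor gene, by 1.48 ± 0.11 and GH3.3, which conjugates auxin, by 1.42 ± 0.07. In all, 1197 of 21626 genes passed, 568 higher and 629 lower. SEN1 was well above background in the overexpressor on 1 of 3 arrays, and TPS04 and AGP30 were so in Col-0 on 2 of 3.

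Of 16 senescence genes, 8 fell in the overexpressor in NaCl and none rose (camera adjusted p = 8.26e-09, 9 lower adjusted over the list alone), among them DIN2 (-1.86 ± 0.45), DIN10 (-1.41 ± 0.15) and the transcription factor gene ORE1 (-1.35 ± 0.11). Of 16 glucosinolate genes, 8 rose, 12 adjusted over the list alone (adjusted p = 2.19e-09), with CYP79F1 at 0.89 ± 0.09 and CYP79B3 at 0.86 ± 0.06. Of 22 jasmonate and ethylene genes, 10 rose and 2 fell, 13 and 2 adjusted over the list alone (adjusted p = 2.17e-06). JAZ10, a repressor gene of jasmonate signalling, rose by 1.27 ± 0.06, while PR4 fell by 1.43 ± 0.05. With an estimated correlation these 3 lists stayed at adjusted p values of 0.0138, 0.00548 and 0.0169. Photosynthesis genes moved down with 6 of 29 lower, RBCS1B at -0.45 and LHCB2.1 at -0.39 (adjusted p = 1.23e-06, lost with an estimated correlation at adjusted p = 0.0591). Auxin response genes moved up with 4 of 12 higher (adjusted p = 0.000434, lost at adjusted p = 0.121), and hypoxia genes moved down with ADH1 and RAP2.3 lower (adjusted p = 0.0141, lost at adjusted p = 0.0816, and 0.136 without replicate 1). Adjusted over the list alone, 9 photosynthesis genes fell, 6 auxin genes rose and 1 fell, and 5 hypoxia genes fell and 1 rose. The list of abscisic acid and osmotic stress genes did not pass (adjusted p = 0.12, but 0.000718 without replicate 2). Of its 37 members 5 rose and 9 fell, 8 and 10 adjusted over the list alone. RAB18 and LEA7 fell by 0.99 and 0.89. KIN1, picked after its value was seen, rose by 0.72. Of the genes known to depend on STOP1, PGIP2 rose by 0.74 ± 0.12 and GDH2 fell by 0.46 ± 0.06, and ALMT1, above background in the overexpressor on 2 of 3 arrays, stood at 0.05 ± 0.09. The 19 lists that did not pass, the abscisic acid list included, had adjusted p values between 0.12 and 0.994. Without replicate 2 the circadian clock list (0.00382) and the CBL and CIPK list (0.0186) passed as well. The count was 430 (32.1% higher, against 47.5%) and 524 without replicate 2 and 3, and 766 with the slide as a block. With median centring in place of loess 109 genes passed (22.9% higher, against 47.5% here), from Agilent's processed signals 1919 and without a dye effect 617. In limma it was 0 within the slide that held 2 of these arrays and 0 on these 3 arrays alone, fits in which 1566 and 4081 genes had an unadjusted p under 0.05 and STOP1 itself did not pass (log2 ratios 4.21 and 4.16). Among these genes the call was lost for DIN2 without replicate 1 and 3 (0.128 and 0.215), RAP2.3 without replicate 1, 2 and 3 (0.0578, 0.0628 and 0.107) and PGIP2 without replicate 2 (0.0777) (adjusted p values in parentheses). The same held for LHCB2.1 without replicate 2 and 3 (0.118 and 0.0803) and RBCS1B without replicate 1, 2 and 3 (0.0501, 0.274 and 0.132).

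The knockout in NaCl had the most calls of the ratio comparisons. GH3.3 rose by 3.09 ± 0.07 on the log2 scale (n = 3), the auxin response gene IAA5 by 3.04 ± 0.07, EM1, a late embryogenesis gene, by 2.98 ± 0.26, TPS04 by 2.52 ± 0.27, AGP30 by 2.33 ± 0.13, BHLH92 by 2.22 ± 0.07 and ERF13 by 2.13 ± 0.08. SEN1 fell by 3.13 ± 0.17, MRD1 by 2.88 ± 0.18, BAM5 by 1.43 ± 0.11, BXL1 by 1.33 ± 0.08 and J8 by 1.24 ± 0.05. In all, 1583 of 21624 genes passed, 1186 higher and 397 lower. TPS04 and AGP30 were well above background in Col-0 on 2 of 3 arrays, and MRD1 was so in the knockout on 1 of 3.

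Of 22 jasmonate and ethylene genes, 16 rose in the knockout in NaCl and 1 fell (camera adjusted p = 3.89e-22), among them JAZ7 (1.93 ± 0.11), TAT3 (1.76 ± 0.15), JAZ10 (1.67 ± 0.06) and AOC1 (1.55 ± 0.09). Of 12 auxin response genes, 6 rose (adjusted p = 8.6e-14), with IAA2 at 1.69 ± 0.07 and IAA19 at 1.37 ± 0.08. Of 37 abscisic acid and osmotic stress genes, 15 rose and none fell (adjusted p = 1.13e-11), with GOLS2 at 1.71 ± 0.20, RD26 at 1.65 ± 0.18 and NCED3, of abscisic acid synthesis, at 1.21 ± 0.11. Heat shock genes moved up with 5 of 13 higher (HSP21 at 1.16 ± 0.15), reactive oxygen genes with 7 of 23 higher and 1 lower (ZAT12 at 1.60 ± 0.11, AOX1A at 1.22 ± 0.07), and cell wall loosening genes with 6 of 19 higher and 1 lower (TCH4 at 1.36 ± 0.10, XTH31 at -1.18 ± 0.29). Their adjusted p values were 1.73e-06, 2.47e-05 and 0.00151. Adjusted over the list alone, 18 jasmonate, 9 auxin, 19 abscisic acid, 10 heat shock, 7 reactive oxygen and 7 cell wall genes rose, and 1 each of all but the auxin list fell. With an estimated correlation these 6 lists stayed at adjusted p values of 0.000816, 0.0122, 0.0224, 0.0371, 0.0371 and 0.0393. The lists of phosphate starvation (PS2 and GDPD1 higher), guard cell markers (none of 8 past the test) and flavonoid genes (PAP1 higher, F3'H lower) passed at adjusted p values of 0.00151, 0.01 and 0.0395 and were lost with an estimated correlation, at adjusted p = 0.0997, adjusted p = 0.0774 and adjusted p = 0.258. Of these lists, adjusted over the list alone, 7 phosphate genes rose, 3 guard cell genes fell, and 1 flavonoid gene rose and 4 fell, and the flavonoid list did not pass without replicate 1 (0.0629) or 2 (0.221). Of the genes known to depend on STOP1, CIPK23 (above background in the knockout on 1 of 3 arrays) fell by 0.59 ± 0.10, PGIP1 by 0.44 ± 0.09 and GDH2 by 0.24 ± 0.06, while PGIP2 rose by 1.24 ± 0.12, and the list did not pass (adjusted p = 0.215). The 16 lists that did not pass, this list included, had adjusted p values between 0.0998 and 0.981, but the photosynthesis list passed without replicate 2 (0.0465) and the senescence list within 1 slide (0.027). The count was 943 without replicate 1, 1333 with the slide as a block and 1827 within the slide that held all 3 arrays, where the jasmonate list had a median of 0.98. Median centring left 288. From Agilent's processed signals 47.8% of 3013 called genes were higher, against 74.9% here. Of the genes named here, the call did not hold for PGIP1 without replicate 2 and 3 (0.162 and 0.0941), GDH2 without replicate 1, 2 and 3 (0.133, 0.129 and 0.141) and XTH31 without replicate 1, 2 and 3 (0.0571, 0.262 and 0.176) (adjusted p values in parentheses). The same held for PAP1 without replicate 1, 2 and 3 (0.0944, 0.0907 and 0.149) and F3'H without replicate 1, 2 and 3 (0.198, 0.223 and 0.0709).

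The effects of each line were then compared between conditions in the same fit. In the overexpressor 537 of 21616 genes differed, 144 with a ratio higher in NaCl than in control and 393 with a lower one. The ratio of SEN1 differed by -3.16 ± 0.23 on the log2 scale (3 arrays per condition), that of GLYI7 by -2.52 ± 0.12, NIT2 by -2.27 ± 0.12, CYP708A2 by -1.87 ± 0.10 and J8 by -1.86 ± 0.07. PS2 differed by 2.29 ± 0.21, PGL5 by 1.89 ± 0.17, ERF13 by 1.63 ± 0.10 and CRF6 by 1.46 ± 0.20. TPS04 also passed upward, but in control it was not well above background in either genotype, so the size is not known. On some arrays a signal was not well above background for GLYI7 and ERF13 in control, SEN1 and ALMT1 in NaCl and HAK5 in both. ALMT1 differed by -1.50 ± 0.12, HAK5 by -1.20 ± 0.14 and GDH2 by -1.07 ± 0.08, so these 3 genes, which rose in control and were picked for this contrast after their values were seen, had lower ratios in NaCl. The lists of senescence genes (median -0.57), root markers (-0.21), hypoxia genes (-0.18) and glucosinolate genes (0.25) passed with the preset and with an estimated correlation (camera adjusted p = 0.024, 0.0294, 0.0324 and 0.0294 with the latter). Of these lists 3, 4 and 1 genes had lower and 2 had higher ratios, and 9, 7, 6 and 2 adjusted over the list alone. The lists of STOP1-dependent (adjusted p = 0.0839), abscisic acid (adjusted p = 0.252), phosphate (adjusted p = 0.0924), photosynthesis (adjusted p = 0.0924), jasmonate (adjusted p = 0.0796) and auxin genes (adjusted p = 0.0848) were past the threshold only with the preset correlation, and the estimated one gave the values in parentheses. Their called members numbered 3, 6, none, 1, 2 and none with lower ratios and none, none, 3, none, 5 and 3 with higher ones, and adjusted over the list alone 6, 8, 1, 4, 2 and none lower and 1, 1, 6, none, 7 and 6 higher. The abscisic acid list did not pass without replicate 1 in NaCl (0.0627). The other 15 lists had adjusted p values between 0.187 and 0.992, but the CBL and CIPK list and the nitrate list passed without replicate 2 in NaCl (each at 0.0325). The count was 36 with median centring (8.3% with a higher ratio, against 26.8% here), 868 from Agilent's processed signals and 312 without a dye effect. It was 354 with the slide as a block, 122 on the 6 arrays alone, and 324, 300 and 332 without replicate 2 in control, replicate 3 in control and replicate 3 in NaCl. With 1 array left out, the difference was not past the threshold for TPS04 without replicate 1 in control, 2 in control, 3 in control, 1 in NaCl and 2 in NaCl (0.0731, 0.0816, 0.0711, 0.0501 and 0.0813) (adjusted p values in parentheses).

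In the knockout 1290 of 21624 genes differed between conditions, 786 with a higher ratio in NaCl and 504 with a lower one. IAA5 differed by 3.18 ± 0.10 on the log2 scale (3 arrays per condition) and GH3.3 by 2.57 ± 0.09. EM1, TPS04 and BHLH92 also passed upward, but in control they were not well above background in either genotype, so the sizes are not known. SEN1 differed by -3.85 ± 0.23, BAM5 by -3.42 ± 0.15, bHLH38 by -2.62 ± 0.22, CYP705A12 by -2.57 ± 0.11 and THAS1 by -2.01 ± 0.17. On some arrays a signal of IAA5 and BAM5 in control, and of bHLH38 in both conditions, was not well above background. Of the STOP1-dependent genes, all picked for this contrast after their values were seen, 5 had a higher ratio in NaCl (9 adjusted over the list alone), PGIP1 among them, PGIP2 by 1.29 ± 0.17 and GDH2 by 0.48 ± 0.08 (camera adjusted p = 9.88e-08, and 0.0144 with an estimated correlation). The others, ALMT1 and STOP2, were not well above background in the knockout in either condition, so the size of their difference is not known. CIPK23 did not differ past the threshold (adjusted p = 0.961) and was well above background in the knockout on 1 of 3 arrays in each condition. Iron deficiency genes differed downward, with 7 of 18 lower (adjusted p = 7e-06), as did root markers with 5 of 20 lower, while jasmonate, auxin, abscisic acid and nitrate genes differed upward with 12, 6, 11 and 4 members higher and 2 jasmonate genes lower. Adjusted over the list alone, 10 iron and 6 root genes had lower ratios and 2 iron genes higher ones, while 15, 8, 16 and 5 of the latter 4 lists had higher ratios and 2 jasmonate and 1 abscisic acid gene lower ones. These 6 lists also passed with an estimated correlation, at adjusted p values of 0.0114, 0.0121, 0.0064, 0.0114, 0.0275 and 0.0275. The lists of GABA and malate (adjusted p = 0.223), cell wall (adjusted p = 0.114), senescence (adjusted p = 0.184), salicylic acid (adjusted p = 0.114), hypoxia (adjusted p = 0.114), heat shock (adjusted p = 0.0989), reactive oxygen (adjusted p = 0.194), flavonoid (adjusted p = 0.194) and ribosomal genes (adjusted p = 0.114) were past the threshold with the preset correlation and lost with the estimated one, at the values in parentheses, and the glucosinolate list came to 0.05. Among these 10 lists, every one but the heat shock and ribosomal lists also missed the threshold without at least 1 array. The cell wall, hypoxia and reactive oxygen lists missed it with the slide as a block (0.0661, 0.0537 and 0.0531). The other 8 lists had adjusted p values between 0.175 and 0.858. The count was 971 with the slide as a block, 603 on the 6 arrays alone, 784, 835 and 746 without replicate 1 in control, replicate 3 in control and replicate 1 in NaCl, and 840 with a normexp offset of 10. Median centring left 117 (49.6% with a higher ratio, against 60.9% here) and a fit without a dye effect 742. From Agilent's processed signals 48.4% of the called genes had a higher ratio. Leaving out arrays ended the call for STOP2 without replicate 2 in control and 1 in NaCl (0.0539 and 0.0502) (adjusted p values in parentheses).

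The salt response of the wild type was taken from the Col-0 channels, with 3 values per condition. LEA7, a late embryogenesis gene, rose by 7.13 ± 0.05 on the log2 scale (SE, n = 3), LTP4, of lipid transfer, by 6.98 ± 0.06, TSPO by 6.06 ± 0.06, GLYI7 by 5.32 ± 0.05, PHI-1 by 5.14 ± 0.11, the alcohol dehydrogenase gene ADH1 by 5.12 ± 0.05, RAB18, a dehydrin gene, by 4.77 ± 0.08 and DFR, of anthocyanin synthesis, by 4.71 ± 0.09. NATA1 also passed upward (adjusted p = 2.44e-06), but it was not well above background in control, so the size is not known. The expansin gene EXPA8 fell by 5.17 ± 0.07, GASA6 by 4.34 ± 0.08, and the levels of MLP329 and AGP30 differed by -3.79 ± 0.05 and -3.71 ± 0.22. In all, 12114 of 21626 genes passed, 5525 higher and 6589 lower, and 2107 of them changed at least 2-fold. Without normalization between arrays 57.0% of the called genes were higher, against 45.6% here, and on the only slide with both conditions 66.0% of 618. In control TSPO, GLYI7 and PHI-1 were well above background in 4, 3 and 5 of 6 Col-0 channels, and AGP30 was so in 4 of 6 with NaCl. The 3 values rest on the assumption that same-numbered Col-0 channels are 1 sample. As given above, their correlations across genes (-0.779 to 0.053) do not favour or settle it. With 6 Col-0 channels per condition 11551 genes passed.

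Of 37 abscisic acid and osmotic stress genes, 30 rose with NaCl in Col-0 and 3 fell, with RD20 at 4.24 ± 0.10. Of 22 jasmonate and ethylene genes, 20 rose (JAZ7 at 4.24 ± 0.06), as did 14 of 16 senescence genes (SAG29 at 4.19 ± 0.07), 11 of 13 heat shock genes (HSP17.4 at 3.00 ± 0.12), 11 of 14 flavonoid genes (PAP1 at 4.28 ± 0.07) and 13 of 23 reactive oxygen genes (ZAT12 at 4.16 ± 0.10). All 20 root tissue markers fell, CASP1 by 2.49 ± 0.07 and TIP2;3 by 2.83 ± 0.27, and so did 12 of 16 glucosinolate genes, 11 of 16 nitrate genes and 13 of 18 phosphate genes, with CYP79F1 at -2.65, NIA1 at -2.49 and PHT1;1 at -2.18. Of the genes known to depend on STOP1, picked here after their values were seen, ALMT1 (-1.32 ± 0.06), STOP2 (-1.27 ± 0.05), NRT1.1 (-1.27 ± 0.17) and GDH1 (-1.20 ± 0.05) fell and HSFA2 rose by 1.59 ± 0.11. Of the genes named here, JAZ7, HSP17.4 and HSFA2 in control were well above background in 4, 3 and 4 of 6 channels, and ALMT1 and STOP2 with NaCl in 5 and 4. With the preset correlation of camera, 10 lists passed, but all were lost with an estimated correlation: abscisic acid (adjusted p = 0.262), jasmonate (adjusted p = 0.13), senescence (adjusted p = 0.281), heat shock (adjusted p = 0.125), flavonoid (adjusted p = 0.125), reactive oxygen (adjusted p = 0.402), root (adjusted p = 0.125), glucosinolate (adjusted p = 0.402), nitrate (adjusted p = 0.347) and phosphate genes (adjusted p = 0.288). The other 15 lists had adjusted p values between 0.0616 and 0.736 with the preset one. Adjusted over the list alone, the counts of these 10 lists were the same as over all genes. Control and NaCl samples met on 1 slide only, where 618 genes passed over its 4 Col-0 channels, the abscisic acid list had a median of 1.64, and the phosphate and reactive oxygen lists did not pass (adjusted p = 0.1 and 0.147). With the slide as a block over all 12 Col-0 channels 8137 genes passed (50.4% higher), and these 2 lists again did not (0.076 and 0.0742). The iron list passed in both of these fits (0.0454 and 0.0131) and the guard cell list in the latter (0.0462).

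Calls were then set side by side between lines and conditions. In the knockout, 179 genes were higher and 56 lower in both conditions, where independent lists would share 37.0 and 5.84 (Fisher's exact test, two-sided, p = 1.11e-74 and 1.96e-38), and 78 went opposite ways. In the overexpressor 27 were higher and 24 lower in both conditions, against 4.07 and 1.86 for independent lists, and 33 were higher in control and lower in NaCl, against 4.51. In control, 29 genes were higher in the overexpressor and lower in the knockout, among them ALMT1, GDH2, ASPGB1 (0.83 and -1.79) and GLN1;4 (0.54 and -0.79), and 21 were lower in the overexpressor and higher in the knockout, among them GASA6 (-1.19 and 0.61), GPT2 (-0.91 and 0.60) and BT2 (-0.76 and 0.84). Independent lists would share 2.28 and 2.00. ASPGB1, GLN1;4, GPT2 and the other genes of this pair of sets were picked after their values were seen. In control, 75 genes were higher in both lines and 8 lower in both. In NaCl, 270 genes were higher in both lines and 152 lower in both, against 31.2 and 11.5 for independent lists, while 78 went opposite ways. These sets shrank when arrays were left out. Without replicate 1, 2 or 3 of the knockout in control, or replicate 1 in NaCl, the same-way set of the knockout was 134, 132, 148 and 144, and without replicate 2 or 3 of the overexpressor in NaCl or replicate 1 of the knockout in NaCl the same-way set of both lines in NaCl was 211, 244 and 275. Without replicate 1, 2 or 3 of the overexpressor in control the same-way set in control was 39, 22 and 33 and the opposite-way set 32, 20 and 28, which was 33, 32 and 30 without replicate 1, 2 or 3 of the knockout in control. With the slide as a block these control sets were 55 and 31. The sets of the overexpressor across conditions (51 the same way and 37 opposite ways) were 22, 16 and 22 and 19, 14 and 17 without replicate 1, 2 or 3 in control, and 32, 25 and 26 and 23, 18 and 24 without replicate 1, 2 or 3 in NaCl. The same-way set was 33 without replicate 3 of the knockout in control and 30 without replicate 1 in NaCl, and with the slide as a block the sets were 29 and 17. The opposite-way set of the knockout was 41, 42 and 45 without replicate 1, 2 or 3 in control, 39 and 43 without replicate 1 or 3 in NaCl and 48 with the slide as a block. That of both lines in NaCl was 35 and 38 without replicate 2 or 3 of the overexpressor, 45, 50 and 48 without replicate 1, 2 or 3 of the knockout and 46 with the slide as a block. Median centring left 35, 1, 1 and 50 genes in the same-way sets of the knockout, the overexpressor, both lines in control and both in NaCl. In control, the call was lost in the overexpressor for GASA6 without replicate 2 (0.109) and GLN1;4 without replicate 2 (0.118) and in the knockout for GASA6 without replicate 1, 2 and 3 (0.235, 0.396 and 0.0551), with adjusted p values in parentheses.

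**Figure D3:**
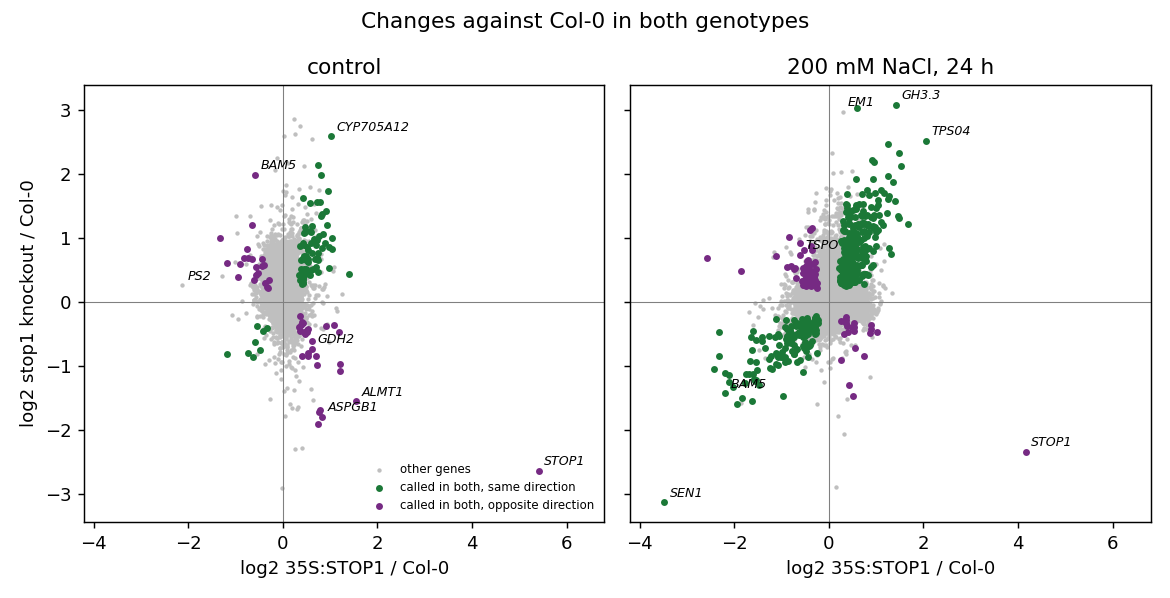
Log2 ratio against Col-0 of each tested gene in 35S:STOP1 (horizontal axis) and in the stop1 knockout (vertical axis), in control (left) and after NaCl (right), with genes called in both lines coloured by whether they changed the same way. In control 83 genes changed the same way and 50 opposite ways, and in NaCl 422 and 78.

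The lines may share Col-0 RNA, which by itself raises such overlaps. That they do is an assumption, which the correlations of same-numbered Col-0 channels do not settle. In 100 simulated sets with no effect and a shared Col-0 value, at most 1 gene was called the same way in both lines, and the covariance of the log2 ratios over genes averaged 0.0102 in each condition. The observed covariance was -0.00304 in control and 0.0132 in NaCl, and the observed correlation, across genes that are not independent replicates, was -0.0862 and 0.211 where the simulation gave 0.524 and 0.523. The Col-0 samples are too few to be split into sets of 2, so part of the excess in NaCl may come from shared controls.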

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

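Of the tests in this part, those of a state of the Col-0 samples, of the root markers and of the STOP1-dependent genes were chosen after the results were seen, and the second root marker test was made after the first had been read.

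The effect of the overexpressor differed between control and NaCl in 537 genes and that of the knockout in 1290 genes by the limma test of the difference itself, with 3 arrays per group. The gene values that follow are differences of log2 ratios, NaCl minus control, past an adjusted p of 0.05 among the named genes. In the overexpressor the ratio was lower in NaCl by over 1 on the log2 scale for SEN1 (-3.16), GLYI7 (-2.52), NIT2 (-2.27), CYP708A2 (-1.87), J8 (-1.86), PR4 (-1.85), MPL1 (-1.73), ELI3-2 (-1.71), MOP10 (-1.64), BAM5 (-1.6), BXL1 (-1.59), MES16 (-1.52), ALMT1 (-1.5), HR4 (-1.39), EXPA7 (-1.36), RHS13 (-1.28), PR3 (-1.28), ORE1 (-1.28), PCC1 (-1.27), STOP1 (-1.25), CYP705A12 (-1.22), PRP3 (-1.2), HAK5 (-1.2), GDH2 (-1.07) and COBL9 (-1.04). It was lower by less for XERO1 (-0.88), LEA7 (-0.81), GPAT5 (-0.8), KC1 (-0.8), RD20 (-0.74), CAT3 (-0.72), GSTU25 (-0.63), ADH1 (-0.62), EXPA18 (-0.58), RAB18 (-0.54) and XTH24 (-0.52). It was higher in NaCl by less than 1 for AOX1A (0.51), EXPA1 (0.53), IAA2 (0.58), BT2 (0.64), IAA5 (0.66), ZAT12 (0.75), CYP79B3 (0.77), CYP79F1 (0.81), GDPD1 (0.89) and GRP3S (0.93). It was higher by more for CYP78A5 (1.04), TAT3 (1.05), GPT2 (1.07), GH3.3 (1.22), JAZ10 (1.27), MGD3 (1.28), ERF1 (1.33), FLR1 (1.41), CRF6 (1.46), ERF13 (1.63), PGL5 (1.89), TPS04 (2.05) and PS2 (2.29). In 1 condition no array had a signal well above background in either genotype for TPS04, ELI3-2 and XERO1, or in 1 genotype for ERF1, TAT3, EXPA18 and PRP3, so the sizes of their differences are not known.

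In the knockout the ratio was lower in NaCl by over 1 for SEN1 (-3.85), BAM5 (-3.42), bHLH38 (-2.62), CYP705A12 (-2.57), THAS1 (-2.01), CYP705A5 (-1.95), ORG1 (-1.95), CYP708A2 (-1.9), BXL1 (-1.89), IOS1 (-1.82), YLS9 (-1.8), bHLH39 (-1.71), J8 (-1.67), CHX17 (-1.63), BHLH100 (-1.56), RAP2.3 (-1.42), ORE1 (-1.34), MT1C (-1.1) and ELI3-2 (-1.06). Smaller negative differences were those of PR3 (-0.97), EXPA7 (-0.95), FRO3 (-0.94), FRK1 (-0.92), EXPA18 (-0.66), GSTU25 (-0.52) and CASP2 (-0.47). Positive differences under 1 were those of EXPA11 (0.35), ADH1 (0.37), CIPK6 (0.4), HSP70 (0.4), GDPD1 (0.41), CIPK15 (0.47), GDH2 (0.48), SOT16 (0.49), XTH19 (0.5), PAP1 (0.53), MYB51 (0.53), HRE1 (0.59), AOC2 (0.64), COR15A (0.68), SARD1 (0.74), NRT1.8 (0.82), AAH (0.83), CYP79B3 (0.85), HB1 (0.86), G6PD3 (0.94), ZAT12 (0.96), STOP2 (0.97) and PAD3 (0.99). Larger ones were those of AOC1 (1.03), XTH18 (1.04), WRKY70 (1.05), PPC3 (1.07), AOX1A (1.11), MGD3 (1.12), ASPGB1 (1.12), HSP21 (1.12), GolS2 (1.15), NCED3 (1.17), PGIP1 (1.2), NRT1.5 (1.21), ALMT1 (1.22), AGP30 (1.26), PGIP2 (1.29), NEET (1.35), NADP-ME2 (1.4), TAT3 (1.44), RD26 (1.46), IAA19 (1.49), JAZ10 (1.54), IAA2 (1.58), GRX480 (1.6), JAZ7 (1.68), TCH4 (1.77), ERF13 (2.07), GSTF14 (2.13), BHLH92 (2.21), TPS04 (2.49), GH3.3 (2.57), EM1 (2.92) and IAA5 (3.18). The sizes are not known for TPS04, EM1, BHLH92, ELI3-2, HSP21 and BHLH100, with no signal well above background in either genotype in 1 condition. The same holds for SARD1, TAT3 and bHLH39, with none in Col-0 in 1 condition, and for ALMT1 and STOP2, with none in the knockout in both.

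Lists that differed between conditions with the preset and with an estimated correlation in camera had these median differences. In the overexpressor they were -0.573 for senescence genes, -0.211 for root markers, -0.178 for hypoxia genes and 0.25 for glucosinolate genes. In the knockout they were 0.74 for jasmonate genes, 0.734 for auxin genes, 0.484 for STOP1-dependent genes, 0.323 for abscisic acid genes, 0.195 for nitrate genes, -0.306 for root markers and -0.539 for iron genes.

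Of 2354 probes without a locus code, which no comparison used, 10 passed the limma test in the overexpressor in control (5 higher and 5 lower), 34 in the overexpressor in NaCl (15 and 19), 29 in the knockout in control (21 and 8) and 46 in the knockout in NaCl (32 and 14).

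For the ratio comparisons, mutant and Col-0 can be exchanged on 1 of 3 arrays, which makes 4 splits with the real one, too few for a share under 0.05; in each, only the real split (1 of 4) gave as many genes. The real split called 219 genes and the highest other 0 for the overexpressor in control, 1197 and 6 for the overexpressor in NaCl, 992 and 0 for the knockout in control and 1583 and 1 for the knockout in NaCl. The 10 splits of 6 samples are also too few, with 537 and 0 for the overexpressor between conditions, 1290 and 0 for the knockout and 12114 and 0 for the salt response of Col-0.

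In NaCl, 422 genes changed the same way in both lines, 270 higher and 152 lower, where independent lists would share 31.2 and 11.5. If Col-0 RNA was shared, its chance values as the whole cause were set against 100 simulated sets. The covariance over genes was 0.0132, where these sets averaged 0.0102 and reached 0.0109. This cannot decide the point, because the simulation did not describe the control arrays. There the observed covariance was -0.00304 and the lowest simulated one 0.00931. In NaCl the observed correlation (0.211) lay below the simulated one (0.523). The controls could not be split, so part of the excess of shared genes may come from them. Dye bias alone is argued against because 188 of 195 genes called the same way without the dye-swapped arrays (96.4%) had that sign on both swapped arrays, where unrelated signs give 25%. A state of the Col-0 NaCl samples, which would move both ratios alike, stays open, since 40.8% of the 422 genes differed between the lines and the rest did not pass that test. An effect that the lines share cannot be told apart from it.

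In control, root tissue markers were higher in both lines, with all 20 above 0 in the knockout and 16 in the overexpressor. Dye bias alone is argued against, since the lower of the 2 lines' marker medians on the swapped arrays was about 0.4 before any dye correction. A larger share of root tissue in the mutant samples may account for it, since epidermis markers (mean 0.53) and endodermis and stele markers (0.47) did not move apart past the threshold (exact permutation test, two-sided, p = 0.687), which does not show that they moved alike. In the second test 5 of 20 markers lay over 3 SE from their weighted mean of 0.48, exactly the number set as its bar, and it decides nothing. Tissue share and a change within roots cannot be told apart here.

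In the knockout, the fitted falls of ALMT1, PGIP1, GDH2 and STOP2 were smaller in NaCl than in control, and these 4 genes were picked after their values were seen (STOP2 missed the limma threshold without replicate 2 in control or 1 in NaCl, at adjusted p = 0.0539 and 0.0502). Signal near background is argued against for PGIP1 and GDH2, both (2 genes) well above background in Col-0 on every knockout NaCl array, and stays open for ALMT1 and STOP2, of which 0 were and which were not well above background in the knockout in either condition. A lower level in salt-treated Col-0 may account for part, since 3 of the genes, ALMT1, GDH2 and STOP2, fell with NaCl in Col-0 (-1.32, -0.48 and -1.27). PGIP1 did not pass (-0.18 ± 0.07, adjusted p = 0.0741), a change far under its difference of 1.2, which argues against that explanation for it. For PGIP1 an effect of NaCl on its dependence on STOP1 stays open as a hypothesis, and cannot be told apart from an effect of the slide.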

How the results depend on the processing

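The alternatives were chosen before the data were examined. The way lists that did not pass were compared, and the genes picked for their values, were chosen after the values were seen. Signal over background limits the dim channel most, with 46.6% to 55.7% of spots well above background in Cy5 and 66.6% to 72.5% in Cy3. In all alternatives but leaving out an array, fits on fewer arrays included, values of named genes kept direction and side of the threshold in 5688 cases, missed the threshold in 769, newly passed in 18 and turned sign in 51. Among called genes the sign turned only for RBCS1A in the overexpressor in NaCl, from processed signals and the series matrix, and for UBQ10 in the Col-0 salt response without normalization between arrays. Lists kept their side of the threshold in 2420 cases, lost a call in 59 and gained one in 64. For lists that did not pass, only the side of the threshold was compared, and their direction differed in 122 of 1995 cases, 0 of them past the threshold. For each value listed here the cause was not tested, except that fits within 1 slide, on the arrays compared or with an array left out use fewer samples and a required 2-fold change admits fewer genes. Median centring and the series matrix gave no value for the salt response. As reported, called genes numbered 219 (overexpressor in control), 992 (knockout in control), 1197 (overexpressor in NaCl), 1583 (knockout in NaCl), 537 (overexpressor between conditions), 1290 (knockout between conditions) and 12114 (Col-0 salt response), and shared sets held 235 (knockout across conditions, same way), 78 (knockout across conditions, opposite way), 51 (overexpressor across conditions, same way), 37 (overexpressor across conditions, opposite way), 83 (both lines in control, same way), 50 (both lines in control, opposite way), 422 (both lines in NaCl, same way) and 78 (both lines in NaCl, opposite way) genes.

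Without background correction, shared sets held 118 (knockout across conditions, opposite way) and 126 (both lines in control, same way). The sign then turned for CIPK23 (0.024, overexpressor in control), SULTR3;5 (0.008, overexpressor in control), ALS3 (-0.006, knockout in control), SULTR3;5 (-0.004, overexpressor in NaCl), SULTR3;5 (-0.013, knockout in NaCl) and CIPK23 (-0.046, knockout between conditions). With a normexp offset of 10, called genes numbered 840 (knockout between conditions). Genes shared then numbered 46 (knockout across conditions, opposite way), 32 (overexpressor across conditions, same way), 55 (both lines in control, same way) and 38 (both lines in NaCl, opposite way). From Agilent's processed signals, called genes numbered 346 (overexpressor in control), 1712 (knockout in control), 1919 (overexpressor in NaCl), 3013 (knockout in NaCl) and 868 (overexpressor between conditions). The shared sets were 501 (knockout across conditions, same way), 200 (knockout across conditions, opposite way), 101 (overexpressor across conditions, same way), 72 (overexpressor across conditions, opposite way), 135 (both lines in control, same way), 80 (both lines in control, opposite way), 653 (both lines in NaCl, same way) and 130 (both lines in NaCl, opposite way). A turned sign was seen for CIPK23 (0.153, overexpressor in control), NAD-ME1 (0.056, knockout in control), HSFA2 (-0.181, knockout in control), ALS3 (-0.659, knockout in control), PGIP2 (0.019, knockout in control), ALMT1 (-0.606, overexpressor in NaCl), NRT1.1 (-0.223, overexpressor in NaCl), CIPK23 (0.344, overexpressor in NaCl) and RBCS1A (0.419, overexpressor in NaCl). With median centring in place of loess, called genes numbered 8 (overexpressor in control), 201 (knockout in control), 109 (overexpressor in NaCl), 288 (knockout in NaCl), 36 (overexpressor between conditions) and 117 (knockout between conditions). Shared sets then held 35 (knockout across conditions, same way), 7 (knockout across conditions, opposite way), 1 (overexpressor across conditions, same way), 0 (overexpressor across conditions, opposite way), 1 (both lines in control, same way), 3 (both lines in control, opposite way), 50 (both lines in NaCl, same way) and 1 (both lines in NaCl, opposite way). The sign then turned for NAD-ME1 (0.054, knockout in control), ALS3 (-0.072, knockout in control), PGIP2 (0.073, knockout in control), HSFA2 (-0.016, overexpressor in NaCl), STOP2 (0.044, overexpressor in NaCl), NAD-ME1 (0.039, knockout in NaCl) and SULTR3;5 (-0.012, knockout in NaCl). Without normalization between arrays, the sign turned for UBQ10 (-0.008, Col-0 salt response). With the mean over the probes of a gene, the sign turned for NRT1.1 (-0.022, overexpressor in NaCl). From the series matrix, called genes numbered 352 (overexpressor in control), 1711 (knockout in control), 1910 (overexpressor in NaCl), 3021 (knockout in NaCl) and 864 (overexpressor between conditions). Shared sets then held 504 (knockout across conditions, same way), 203 (knockout across conditions, opposite way), 101 (overexpressor across conditions, same way), 71 (overexpressor across conditions, opposite way), 135 (both lines in control, same way), 80 (both lines in control, opposite way), 650 (both lines in NaCl, same way) and 128 (both lines in NaCl, opposite way). The sign then turned for CIPK23 (0.154, overexpressor in control), NAD-ME1 (0.054, knockout in control), HSFA2 (-0.18, knockout in control), ALS3 (-0.658, knockout in control), PGIP2 (0.019, knockout in control), ALMT1 (-0.605, overexpressor in NaCl), NRT1.1 (-0.224, overexpressor in NaCl), CIPK23 (0.344, overexpressor in NaCl) and RBCS1A (0.419, overexpressor in NaCl). Without a dye effect, called genes numbered 127 (overexpressor in control), 620 (knockout in control), 617 (overexpressor in NaCl), 312 (overexpressor between conditions) and 742 (knockout between conditions). Genes shared then numbered 124 (knockout across conditions, same way), 41 (knockout across conditions, opposite way), 20 (overexpressor across conditions, same way), 16 (overexpressor across conditions, opposite way), 48 (both lines in control, same way), 30 (both lines in control, opposite way), 239 (both lines in NaCl, same way) and 29 (both lines in NaCl, opposite way). Signs turned for HSFA2 (-0.029, overexpressor in control), HSFA2 (-0.028, knockout in control), ALS3 (-0.065, knockout in control), PGIP2 (0.002, knockout in control) and TMT2 (-0.022, overexpressor in NaCl). With the slide as a block, called genes numbered 138 (overexpressor in control), 766 (overexpressor in NaCl) and 354 (overexpressor between conditions). The shared sets were 48 (knockout across conditions, opposite way), 29 (overexpressor across conditions, same way), 17 (overexpressor across conditions, opposite way), 55 (both lines in control, same way), 31 (both lines in control, opposite way) and 46 (both lines in NaCl, opposite way). A turned sign was seen for HSFA2 (-0.01, overexpressor in control) and HSFA2 (-0.009, knockout in control). Within 1 slide, called genes numbered 2 (overexpressor in control), 0 (knockout in control) and 0 (overexpressor in NaCl). The log2 ratio of STOP1 then missed the threshold at -2.691 (knockout in control) and 4.213 (overexpressor in NaCl). Every shared set then held 0 genes. The sign then turned for HSFA2 (-0.013, overexpressor in control), ALMT1 (-0.012, overexpressor in NaCl), ALS3 (0.048, overexpressor in NaCl), HAK5 (-0.066, overexpressor in NaCl), TMT2 (-0.013, overexpressor in NaCl) and SULTR3;5 (-0.064, overexpressor in NaCl). With only the arrays compared, called genes numbered 2 (overexpressor in control), 3647 (knockout in control), 0 (overexpressor in NaCl), 122 (overexpressor between conditions) and 603 (knockout between conditions). The log2 ratio of STOP1 then missed the threshold at 4.156 (overexpressor in NaCl). Genes shared then numbered 406 (knockout across conditions, same way), 156 (knockout across conditions, opposite way), 0 (overexpressor across conditions, same way), 0 (overexpressor across conditions, opposite way), 0 (both lines in control, same way), 2 (both lines in control, opposite way), 0 (both lines in NaCl, same way) and 0 (both lines in NaCl, opposite way). Signs turned for HSFA2 (-0.013, overexpressor in control), SULTR3;5 (-0.002, overexpressor in NaCl) and STOP2 (0.001, overexpressor in NaCl). With a change of at least 2-fold required as well, called genes numbered 17 (overexpressor in control), 132 (knockout in control), 102 (overexpressor in NaCl), 243 (knockout in NaCl), 126 (overexpressor between conditions), 281 (knockout between conditions) and 2107 (Col-0 salt response). On the Col-0 channels of the slide with both conditions, called genes numbered 618 (Col-0 salt response). There, and with 12 Col-0 channels and the slide as a block, the sign of STOP1 turned (-0.031).

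The share of higher calls moved by over 10 points in some alternatives. From processed signals it was 53.0% (67.9% as reported) for the knockout in control, 47.8% (74.9%) for the knockout in NaCl and 48.4% (60.9%) for the knockout between conditions, and these 3 were, from the series matrix, 53.1%, 47.9% and 48.4%. With median centring it was 50% (70.8%) for the overexpressor in control, 22.9% (47.5%) in NaCl and 8.3% (26.8%) between conditions, and 49.6% for the knockout between conditions. Without normalization between arrays it was 57.0% (45.6%) for Col-0. On the Col-0 channels of the slide with both conditions it was 66.0% (50.4% with the slide as a block), on only the arrays compared 84.8% for the knockout in control, and without replicate 2 32.1% for the overexpressor in NaCl. The fits that called at most 2 genes are left aside here.

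Leaving out 1 array at a time gave these ranges, a lone remaining orientation being assumed to vary like the other groups: overexpressor in control calls 61 to 101, STOP1 in overexpressor in control 5.333 to 5.633, overexpressor between conditions calls 300 to 389, knockout in control calls 433 to 584, STOP1 in knockout in control -2.691 to -2.595, knockout between conditions calls 746 to 1067, overexpressor in NaCl calls 430 to 1012, STOP1 in overexpressor in NaCl 4.1 to 4.213, knockout in NaCl calls 943 to 1166, STOP1 in knockout in NaCl -2.589 to -2.229, knockout across conditions, same way 132 to 230, knockout across conditions, opposite way 39 to 77, overexpressor across conditions, same way 16 to 50, overexpressor across conditions, opposite way 14 to 34, both lines in control, same way 22 to 78, both lines in control, opposite way 20 to 46, both lines in NaCl, same way 211 to 384, both lines in NaCl, opposite way 35 to 70, Col-0 salt response calls 9269 to 12943. The sign of uncalled genes turned in these ranges: PGIP2 -0.012 to 0.085 (overexpressor in control), SULTR3;5 -0.089 to 0.091 (overexpressor in control), STOP2 -0.18 to 0.164 (overexpressor in control), CIPK23 -0.068 to 0.004 (overexpressor in control), HSFA2 -0.06 to 0.152 (overexpressor in control), NAD-ME1 -0.067 to 0.066 (knockout in control), ALS3 -0.383 to 0.223 (knockout in control), PGIP2 -0.111 to 0.087 (knockout in control), CIPK23 -0.076 to 0.172 (knockout between conditions), STOP2 -0.217 to 0.095 (overexpressor in NaCl), NRT1.1 -0.314 to 0.625 (overexpressor in NaCl), HSFA2 -0.085 to 0.377 (overexpressor in NaCl), ALMT1 -0.012 to 0.097 (overexpressor in NaCl), ALS3 -0.422 to 0.048 (overexpressor in NaCl), HAK5 -0.066 to 0.185 (overexpressor in NaCl), TMT2 -0.013 to 0.022 (overexpressor in NaCl), SULTR3;5 -0.064 to 0.079 (overexpressor in NaCl), SULTR3;5 -0.015 to 0.09 (knockout in NaCl), NRT1.1 -0.593 to 0.002 (knockout in NaCl), NAD-ME1 -0.098 to 0.066 (knockout in NaCl). Named genes, called or not, kept direction and side of the threshold in 1539 cases, missed the threshold in 206 and turned sign in 25, and lists kept their side in 706, lost a call in 36 and gained one in 8.

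Same-numbered arrays correlated at -0.722 to 0.495 in their deviations from the group means, with both signs among replicates 1 and 3. No steady pairing by replicate number was seen there. For replicate 2 the check cannot tell, because it is the swapped array of every group. A deviation shared by the replicate 2 arrays was thus removed with the dye effect. With a replicate block the overexpressor's same-way set across conditions held 29 genes in place of 51, and no count of calls moved by over 1.5 times.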

Other observations

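The genes in this part were picked after their values were seen, and the tests on them are those of limma over all genes.

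Genes of the thalianol cluster (THAS1, CYP708A2 and CYP705A5) and of the marneral cluster (MRN1, CYP705A12 and CYP71A16), which make root triterpenes, were higher in both lines in control. In the knockout all 6 rose, from 1.55 ± 0.11 for MRN1 to 2.60 ± 0.08 for CYP705A12 on the log2 scale (SE, n = 3) and none lost its call with 1 array left out. In the overexpressor all 6 rose, from 0.57 ± 0.11 for MRN1 to 1.01 ± 0.08 for CYP705A12, but THAS1 and MRN1 lost the call without any 1 of the 3 arrays (adjusted p up to 0.236 and 0.46), CYP705A5 without replicate 1 or 2 (0.134 and 0.234) and CYP71A16 without replicate 2 (0.0701). CYP708A2 and CYP705A12 held with each array left out. In NaCl 0 of the 6 rose in either line, and in the overexpressor CYP708A2 fell by 0.91 ± 0.07 (adjusted p = 7.11e-05) while THAS1 fell by 0.53 ± 0.12 (adjusted p = 0.0353), a call lost without any 1 of the arrays (adjusted p up to 0.181). The ratios of all 6 differed between conditions in both lines, from -0.74 ± 0.15 for MRN1 to -1.87 ± 0.10 for CYP708A2 in the overexpressor, where MRN1 lost its call without replicate 1, 2 or 3 in control (0.0742, 0.165 and 0.133) and without replicate 1 or 3 in NaCl (0.0962 and 0.0844), and from -1.29 ± 0.12 for CYP71A16 to -2.57 ± 0.11 for CYP705A12 in the knockout. In NaCl CYP705A5, MRN1 and CYP71A16 were not well above background on some arrays in both lines. Root tissue markers were also higher in both lines in control.

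Of the genes that went opposite ways in NaCl, LEA7 (-0.89 ± 0.07 in the overexpressor and 0.55 ± 0.07 in the knockout), TSPO (-0.62 ± 0.08 and 0.75 ± 0.08) and RD20 (-0.73 ± 0.07 and 0.51 ± 0.07) also rose with NaCl in Col-0, by 7.13, 6.06 and 4.24 (TSPO above background in 4 of 6 Col-0 control channels). From Agilent's processed signals TSPO did not pass in either line (adjusted p = 0.097 and 0.101).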
